A study of Mus musculus with 4 samples.

How the data were processed

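RNA was sequenced from small-intestinal adenomas of mice carrying the Apc Min allele, in which one copy of the tumour suppressor Apc is truncated. There were 4 libraries, 2 from mice with the Apc allele alone (control) and 2 from mice that also carried a PAF knockout. RNA was extracted with a column kit and libraries were made with Illumina protocols, per the labels' protocols. The authors deposited one table of FPKM values (fragment counts scaled by transcript length and by the total of mapped fragments) with a column per library. TopHat2, Cuffdiff and the mouse build mm9 are named in the submitters' processing notes; versions, settings and the gene annotation are not given in the sources used here. FPKM values are already scaled for depth and transcript length, so a test for counts was not used.

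The table held 29955 rows. Of these, 84 repeated a symbol and the row with the higher mean was kept, which left 29871. Symbols were upper case in the table and were matched to mouse symbols, gene classes and chromosomes through a RefSeq gene table of assembly GRCm38.p6. Transcript length and GC content came from the longest GENCODE transcript on GRCm38. Because the build of the table differs, no coordinates were used. Among the 13716 tested rows, 11458 matched by current symbol, 1508 by synonym and 750 not at all. Some synonyms give a second row for a gene that also stands under its current symbol. Length and GC content were found for 99.8% of the tested protein-coding rows.

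Depth was estimated from genes with 1 transcript of at least 1000 bases. The most common low value of FPKM times length in kb, within a preset range, was taken as the worth of 1 fragment. This gave about 13100000 and 17500000 fragments for the control libraries and 15400000 and 24100000 for the knockout libraries. Gapdh, an abundant glycolytic enzyme, was listed at 0.832 to 1.60 FPKM, while Actb was listed at 1454 to 2335. Gapdh has many near-identical copies in the genome. Whether such genes are listed too low was not tested, so their values are taken as uncertain. Exact values of 0 can be failed estimates, and such rows are described as listed at 0.

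Rows with a mean of at least 1 FPKM over the 4 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with moderated variances and a trend on mean expression. P-values were adjusted by the Benjamini-Hochberg method over the tested rows, and rows with an adjusted p under 0.05 were called. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The labels do not say that libraries came from separate animals. The knockout libraries differed in sex-linked transcripts and so held RNA of different animals. Nothing shows this for the control libraries, whose spread may be technical. The limma p-values of single rows measure only the spread between these samples.

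Before the data were examined, 38 gene lists were written, covering pathways and markers of cell types that the samples could hold. They were tested with camera in limma, 2-sided, with a preset correlation between genes of 0.01 and adjustment over the 38 lists. An estimated correlation and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were run beside it. With the preset correlation, camera compares a list's genes with the other genes. Such p-values rest on the spread over genes and do not measure the spread between animals. Genes named in the text were the PAF gene, 18 fixed genes of the intestine and of Wnt signalling, in each direction up to 12 called genes with the largest change and no overlap between groups (or, where fewer than 5 were called, those of smallest p up to 5), and the 3 members of smallest p in each list described. Genes outside this rule are named as chosen after their values were seen. Rows without a gene symbol were skipped, apart from a pair of called rows named to complete a count.

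The steps were tested on simulated data, 10 sets of 13716 rows with the observed spread within each group, in which 200 genes had been changed for the comparison of PAF knockout with control. The share of changed genes recovered was 0% for a log2 change of 1, 3.0% for 2, 36.2% for 3 and 78.2% for 5, with a mean of 0.9 false calls per set. A list shifted by a log2 change of -0.8 was called in 10 of 10 sets by camera with the preset correlation and in 0 with the estimated one. Deviations were drawn for each gene independently, so the simulated lists held no correlation between genes. In the data the estimated correlation was 0.02 for the Wnt/beta-catenin list and 0.765 for the DNA damage repair list. The simulation therefore cannot decide which correlation is right for the data. It does show that the estimated setting missed a true shift even without correlation between genes. A list left uncalled by that setting is therefore no evidence against a change.

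Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a filter at 5 FPKM, quantile scaling, median centring, TPM, no variance trend, robust variances, the replicate number as a block, each library left out, and another threshold on p or fold change. Those added after seeing the data were protein-coding rows alone, removal of a trend on GC content and transcript length from each library, the control libraries averaged as 1 sample, and a block with crossed replicate numbers.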

Results

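The series compared mRNA in adenomas of Apc Min mice with and without PAF, taken here from knowledge of the study as the PCNA-associated factor encoded by Pclaf (row 2810417H13Rik). Each group had 2 libraries. FPKM values summed to 528147 and 533824 in the control libraries and to 543952 and 609635 in the knockout libraries. The control libraries differed by a median of 0.09 on the log2 scale over tested rows (Pearson r across genes 0.958), and the knockout libraries by 0.49 (r = 0.821). The first principal component held 64.3% of the variance and set knockout library 2 apart from the rest. That library held Xist, the transcript that silences an X chromosome in females, at 46.4 FPKM and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty at 0. In the other 3 libraries Xist was at most 0.00861 FPKM and Eif2s3y lay between 26.0 and 31.7 FPKM, so sex differed within the knockout group.

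The PAF transcript was present at a lower level in both knockout libraries. Row 2810417H13Rik read 17.9 and 17.8 FPKM in the controls, and 4.13 and 11.4 FPKM in the knockouts, which is 23.2% and 63.9% of the control mean. The log2 fold change was -1.24 (SE 0.484, n = 2 per group; limma adjusted p = 0.398) and was not past the threshold. The altered part of the gene is not given in the sources used here, so reads from a remaining part of the transcript are not excluded and the row is a weak check of the labels. Paf1, another gene the abbreviation could name, read 26.4 and 26.4 FPKM in the controls and 25.3 and 28.6 in the knockouts. Pafah1b1 read 52.3 FPKM in knockout library 2 and 27.4 to 32.2 in the others, and Ptafr was at most 1.84 FPKM.

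The comparison of genotypes called 10 of 13716 rows, all lower in the knockout adenomas. Of these, 8 were rows of microRNAs or small nucleolar RNAs, which guide modification of ribosomal and other RNA: Snord42b, Snord58b, Mir22, Snord47, Mir3074-1, Mir2861, Snord88c and Mir3061. Mir22 read 453 and 532 FPKM in the controls and was listed at 0 in both knockouts (limma adjusted p = 0.00661), and Snord47 read 416 and 313 FPKM and was likewise listed at 0 (adjusted p = 0.0121). The other called rows, AK213200 and MKIAA0031, matched no gene in the reference table. In all, 9 of the 10 called rows were listed at 0 in both knockout libraries. Among protein-coding rows alone limma called 0 genes, and over all rows 1810 had an unadjusted p under 0.05 (472 higher and 1338 lower) where 686 would be expected with no change. The count was 0 without either control library, 8397 without knockout library 1 and 2833 without knockout library 2, where the lone knockout sample is assumed to vary like the controls.

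Genes of smallest p among those higher in the knockout adenomas were not past the threshold. Dmbt1, a mucosal scavenger receptor, read 96.8 and 97.3 FPKM in the controls and 441 and 427 in the knockouts (log2 fold change 2.15, SE 0.171; limma adjusted p = 0.175). Ccl2, a chemokine for monocytes, read 3.89 and 3.53 against 33.4 and 24.9 FPKM. Cps1, which makes carbamoyl phosphate for the urea cycle, read 46.2 and 44.0 against 200.2 and 236 FPKM. Hoxa7 and Chit1, a chitinase, had log2 fold changes of 2.25 and 1.73 (limma adjusted p = 0.178 for each).

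Targets of Wnt/beta-catenin signalling, the pathway that loss of Apc activates, fell as a list in the knockout adenomas. The median log2 fold change over 38 tested members was -0.81, with medians of -0.98 in knockout library 1 and -0.86 in knockout library 2 (camera adjusted p = 1.21e-09; adjusted p = 0.762 with an estimated correlation). Adjusted over the list alone, 22 members were lower, 0 were higher and 16 did not pass, while 0 passed over all genes tested. Wif1, a secreted Wnt inhibitor, read 322 and 316 FPKM in the controls and 65.3 and 71.3 in the knockouts, a log2 fold change of -2.21 (SE 0.171). The ligand Wnt6 read 16.2 and 13.9 against 3.69 and 3.27 FPKM, and the Wnt inhibitor Apcdd1 read 40.1 and 41.5 against 14.1 and 13.9. Axin2, a feedback inhibitor, read 122 and 118 FPKM in the controls and 44.9 and 27.9 in the knockouts. Myc had a log2 fold change of -0.75 (SE 0.189) and Ascl2 of -0.66 (SE 0.147). Sox9 read 153 and 157 FPKM in the controls, 122 in knockout library 1 and 51.9 in knockout library 2, and its log2 fold change of -0.95 (SE 0.468) was -0.34 without the latter library. Other members had smaller differences or lay higher, with log2 fold changes of 0.26 for the adhesion receptor Cd44 (SE 0.157), -0.28 for Ccnd1 (SE 0.317), 0.14 for Ctnnb1, which encodes beta-catenin (SE 0.296), and -0.10 for Apc (SE 0.157). With 1 knockout library left out, the value of Ccnd1 was -0.66 or 0.10, that of Ctnnb1 -0.17 or 0.45 and that of Apc -0.18 or -0.032. Lgr5, a receptor on stem cells, read 32.1 and 32.7 FPKM in the controls and 26.5 and 37.7 in the knockouts.

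**Figure D1:**
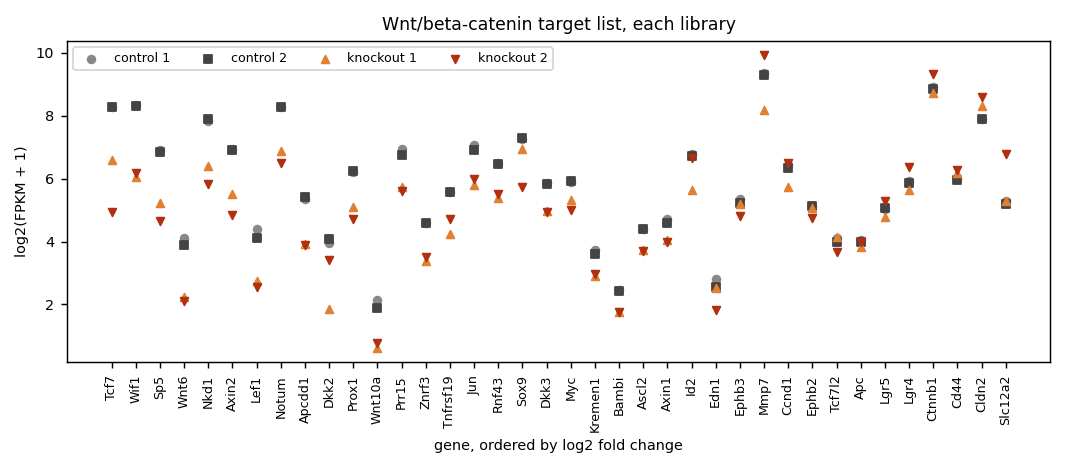
Points give log2(FPKM + 1) on the vertical axis for each of the 38 tested Wnt/beta-catenin target genes on the horizontal axis, 1 point per library. Both knockout libraries lie below both control libraries for 29 genes and above them for 3.

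Intestinal stem cell markers were not called as a list (median -0.12 over 29 genes; camera adjusted p = 0.413), and the medians had opposite signs in knockout library 1 (-0.26) and knockout library 2 (0.19). Adjusted over the list alone, 7 members were lower and 1 was higher, and 0 passed over all genes. The members of smallest p were Znrf3, Rnf43 and Axin2, with log2 fold changes of -1.17, -1.05 and -1.73, all also Wnt targets. Olfm4 read 36.9 and 31.2 FPKM in the controls, 45.3 in knockout library 1 and 174 in knockout library 2.

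Lists of proliferation and DNA repair genes were called higher. Genes of mitosis and G2/M had a median log2 fold change of 0.44 over 33 members, 0.20 and 0.69 in the knockout libraries (camera adjusted p = 1.41e-06; adjusted p = 0.762 with an estimated correlation). DNA replication genes and PAF partners had a median of 0.25 over 45 members, but -0.03 in knockout library 1 and 0.53 in knockout library 2 (adjusted p = 0.00557; adjusted p = 0.762 with an estimated correlation). DNA damage repair genes had a median of 0.19 over 30 members, -0.01 and 0.41 in the knockout libraries (adjusted p = 0.0115; adjusted p = 0.784 with an estimated correlation). The median over all tested rows was -0.11 in knockout library 1 and 0.09 in knockout library 2, and list medians were not adjusted for it. The repair call was lost with a filter at 5 FPKM (adjusted p = 0.219), with the GC and length trend removed (median 0.13, adjusted p = 0.0784) and without knockout library 2 (adjusted p = 0.291), and the replication call without knockout library 2 (adjusted p = 0.160). Adjusted over the list alone, 0 members of each of these lists passed, as over all genes (limma; 1810 of all tested rows had an unadjusted p under 0.05). Members of smallest p included Birc5, an inhibitor of apoptosis active in mitosis, at 32.4 and 37.6 FPKM in the controls and 56.3 and 79.9 in the knockouts, Tk1, a thymidine kinase, at 9.48 and 10.99 against 17.1 and 22.3 FPKM, and Fancb, with a log2 fold change of 0.72 (SE 0.243). Mki67 had a log2 fold change of 0.46 (SE 0.206), Pcna of 0.15 (SE 0.176) and the cell cycle inhibitor Cdkn1a of -0.79 (SE 0.502). Without knockout library 2 these values were 0.26, 0.032 and -0.14, and without knockout library 1 they were 0.65, 0.26 and -1.45. That of Pcna turned negative with the GC and length trend removed. Myc targets and ribosome biogenesis genes were not called (median 0.22, with 0.012 and 0.41 in the knockout libraries; camera adjusted p = 0.0563), but were called higher in 7 of 20 alternative settings, such as with the GC and length trend removed (median 0.20, adjusted p = 0.00729), without knockout library 2 (adjusted p = 0.0445) and without control library 2 (adjusted p = 0.0292). The p53 targets were not called (median -0.10, with -0.20 and 0.047 in the knockout libraries; adjusted p = 0.250).

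Among 5 metabolic lists, 2 were called. Oxidative phosphorylation genes rose, with a median of 0.53 over 44 members, 0.37 and 0.76 in the knockout libraries (camera adjusted p = 2.33e-07; adjusted p = 0.762 with an estimated correlation), and 35 members were higher in both knockouts than in both controls. Sdha, of the succinate dehydrogenase complex, read 98.3 and 96.7 FPKM in the controls and 136 and 155 in the knockouts. Fatty acid uptake and oxidation genes had a median of 0.18 over 30 members, with 0.46 in knockout library 1 and -0.30 in knockout library 2 (adjusted p = 0.0244; adjusted p = 0.762 with an estimated correlation). That call was kept in 10 of 20 alternative settings and lost, for example, under quantile scaling (adjusted p = 0.0888), median centring (adjusted p = 0.0591), without control library 1 (adjusted p = 0.0985) or 2 (adjusted p = 0.0664) and without knockout library 1 (median -0.30, adjusted p = 0.240). The fatty acid receptor Cd36 read 1.66 and 2.04 against 4.98 and 4.58 FPKM. Adjusted over the list alone, 0 members of either list passed, as over all genes (limma). Glycolysis and hypoxia genes (median -0.35; adjusted p = 0.364), cholesterol synthesis genes (median -0.23; adjusted p = 0.178) and xenobiotic and retinoid metabolism genes (median -0.39, where camera gave the direction as higher; adjusted p = 0.611) were not called, and their medians differed between the knockout libraries. They were 0.019 and -0.58 for glycolysis and hypoxia, which was called without knockout library 1 (adjusted p = 0.00728), and -0.30 and -0.084 for cholesterol synthesis, which was called without knockout library 2 (adjusted p = 0.00699). For xenobiotic and retinoid metabolism they were 0.69 and -1.08, and each knockout library alone gave a call, higher for library 1 (adjusted p = 1.61e-08) and lower for library 2 (adjusted p = 0.00105).

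Inflammatory cytokine and acute response genes rose, with a median of 0.90 over 27 members and 1.28 and 0.42 in the knockout libraries (camera adjusted p = 0.000785; adjusted p = 0.762 with an estimated correlation). Its median was 0.41 with no filter, and without knockout library 1 the call was lost (median 0.42, adjusted p = 0.251). Adjusted over the list alone, 9 were higher and 2 lower, and 0 passed over all genes. Saa3, an acute phase protein, read 67.4 and 78.1 FPKM in the controls and 219 and 215 in the knockouts, and the cytokine Il1b read 5.43 and 5.42 against 26.4 and 17.3. Neutrophil markers rose by a median of 1.504 over the 8 of 18 listed genes that passed the filter, 1.77 and 1.24 in the knockout libraries (adjusted p = 0.000136; adjusted p = 0.762 with an estimated correlation), and 6 were higher adjusted over the list alone. With no filter the median was 0.73, and without knockout library 1 the call was lost (adjusted p = 0.130). S100a8 read 6.59 and 13.2 against 63.1 and 51.0 FPKM, and both it and Il1b stand in both lists. Mast cell markers fell by a median of 0.89 over 13 members, 6 of them lower adjusted over the list alone (adjusted p = 0.000136; adjusted p = 0.762 with an estimated correlation). The mast cell proteases Mcpt4 and Cma1 had log2 fold changes of -1.65 (SE 0.169) and -1.09 (SE 0.160). T cell and NK markers had a median of -0.64 over 14 members, -0.94 and -0.48 in the knockout libraries, 4 of them lower adjusted over the list alone (adjusted p = 0.00114; adjusted p = 0.762 with an estimated correlation). With no filter the median was -0.37, and without knockout library 1 the call was lost (adjusted p = 0.0847). The granzyme Gzmb read 31.2 and 27.8 against 13.1 and 13.1 FPKM. Over all genes tested, 0 members of the neutrophil, mast cell and T cell lists passed (limma).

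Markers of epithelial and stromal cells moved in several directions. Goblet cell markers rose by a median of 0.47 over 22 members, 0.34 in knockout library 1 and 0.81 in knockout library 2 (camera adjusted p = 0.000163; adjusted p = 0.762 with an estimated correlation), with 0 passing adjusted over the list alone (limma). The mucin Muc2 read 170 and 174 FPKM in the controls and 346 and 332 in the knockouts, and Agr2, which folds mucins, read 554 and 548 against 1480 and 2105. Absorptive enterocyte markers fell as a list, with a median of -0.96 over 32 members, but the medians were 0.26 in knockout library 1 and -1.67 in knockout library 2 (adjusted p = 0.00141; adjusted p = 0.762 with an estimated correlation). Without knockout library 2 the list was called higher (adjusted p = 0.0414). The enterocyte phosphatase Alpi showed this split, at 102 and 104 FPKM in the controls, 510.5 in knockout library 1 and 12.9 in knockout library 2, while the sucrase Sis read 180.4 and 171 against 71.8 and 56.4. Markers of the distal small intestine fell by a median of 1.18 over 13 members, with -1.62 in knockout library 1 and -0.36 in knockout library 2 (adjusted p = 0.0295; adjusted p = 0.762 with an estimated correlation), and Cubn, a receptor for vitamin B12 uptake, read 12.9 and 13.02 against 0.875 and 1.62 FPKM. Proximal markers were not called (adjusted p = 0.988), with medians of 1.331 and -1 in the knockout libraries, each called when that library alone stood for the knockouts (adjusted p = 0.000167 and 0.00476). The distal call was lost with no filter (adjusted p = 0.0699) and without knockout library 1 (adjusted p = 0.170). Fibroblast markers had a median of 0.48, with 0.20 in knockout library 1 and 0.63 in knockout library 2 (adjusted p = 0.00339), smooth muscle markers of 0.73 (adjusted p = 0.0132) and endothelial markers of 0.34 (adjusted p = 0.0189), each with adjusted p = 0.762 with an estimated correlation. The endothelial call was kept in 13 of 20 alternative settings and lost without control library 1 (adjusted p = 0.0568) and without knockout library 1 (adjusted p = 0.0740). Smooth muscle medians were 0.13 and 1.34 in the knockout libraries, the call was lost without knockout library 2 (adjusted p = 0.0918), and Myh11 read 7.08 and 6.37 FPKM in the controls, 10.5 in knockout library 1 and 45.1 in knockout library 2. Adjusted over the list alone, 4 enterocyte members and 3 distal members were lower, 2 endothelial members were higher and 2 lower, and 0 fibroblast or smooth muscle members passed; over all genes 0 passed in any of these lists (limma). Of the fixed markers, Lyz1 of Paneth cells, Chga of enteroendocrine cells and Dclk1 of tuft cells had log2 fold changes of 0.26 (SE 0.280), -0.22 (SE 0.285) and -0.06 (SE 0.613). Without knockout library 2 they were 0.020, 0.12 and -0.88, and without knockout library 1 they were 0.50, -0.56 and 0.76. With the GC and length trend removed Lyz1 turned negative and Chga positive, and Dclk1 turned positive under quantile scaling.

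**Figure D2:**
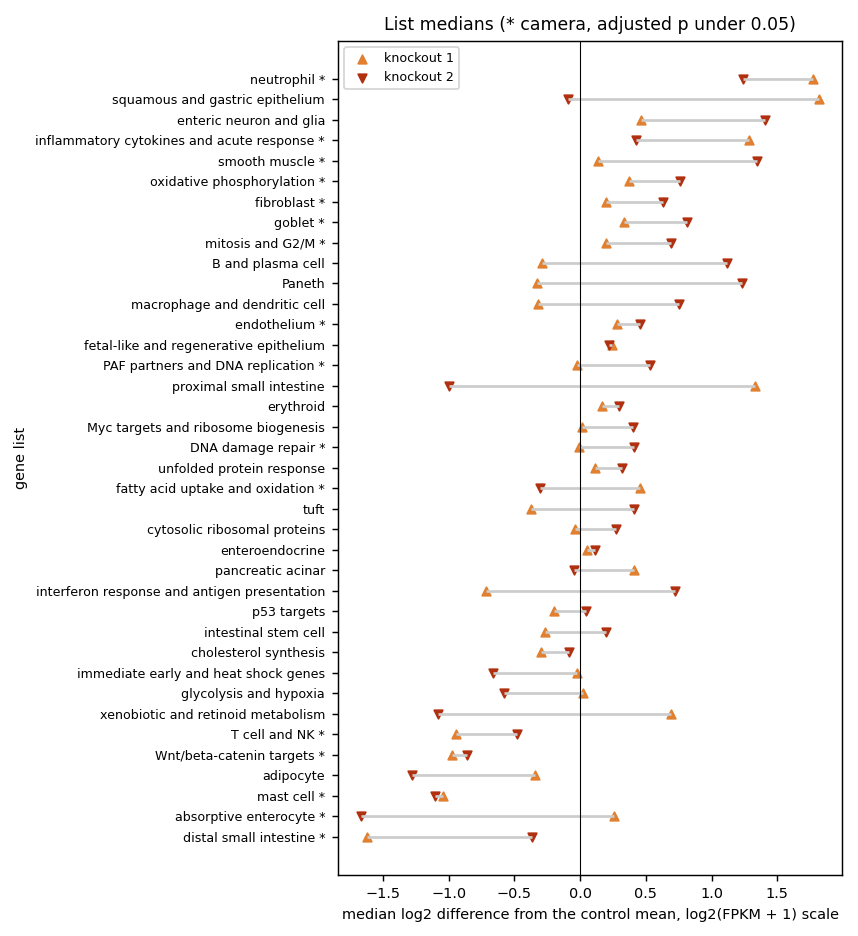
Each line of the plot is 1 of the 38 gene lists, and the triangles give its median log2 difference from the control mean in each knockout library on the horizontal axis. For 12 of the 16 called lists, marked with an asterisk, both medians have one sign, while the medians of the absorptive enterocyte list are 0.26 and -1.67. Signs are not adjusted for the medians over all tested rows, -0.11 in knockout library 1 and 0.09 in knockout library 2.

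Of the 38 lists, 16 were called by camera with the preset correlation, 11 higher and 5 lower. With an estimated correlation 0 were called (lowest adjusted p = 0.762), and fry called 0 (lowest adjusted p = 0.0529). The estimated setting also called the shifted list in 0 of 10 simulated sets, so its lack of calls does not speak against a list.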

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

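Results for protein-coding rows, GC and length removal, averaged controls and the crossed block were chosen after seeing the data. The count of 10 called rows was 8 to 13 under most settings, 4 with no filter, 6 with the GC and length trend removed, and 0 with protein-coding rows alone or with the controls averaged as 1 sample; with each library left out it ranged from 0 to 8397. The replicate block gave 13 calls and 18 lists, and the crossed block 13 and 16. Deviations of libraries with the same number correlated at -0.115, which gives no sign of pairing. The control libraries differed little from each other, so a shared effect could go unseen and pairing is not excluded. List calls numbered 15 to 21, except 0 with an estimated correlation and 0 by fry. The PAF transcript ranged from -1.88 to -0.60 with a library left out. The Wnt list kept its call in 18 of 20 settings (medians -0.98 to -0.74). Directions reversed for Lgr5 (0.008) and Dclk1 (0.006) under quantile scaling, Lgr5 (0.022) under median centring, and Pcna (-0.23), Lyz1 (-0.053) and Chga (0.038) with the GC and length trend removed; the cause was not tested. Quantile scaling shifted the median of knockout library 1 by 0.12, median centring by 0.13, and TPM shifted that of library 2 by -0.19. Under TPM the list medians were 0.14 for DNA replication, 0.10 for DNA damage repair and 0.09 for fatty acid uptake and oxidation. They were 0.25, 0.19 and 0.18 in the main setting, and these calls were kept. With a library left out, ranges that crossed 0 among the fixed genes and the called lists were, in log2 units, Lgr5 -0.28 to 0.21, Ccnd1 -0.66 to 0.10, Dclk1 -0.88 to 0.76, the fatty acid uptake and oxidation list -0.30 to 0.46, Ctnnb1 -0.17 to 0.45, Chga -0.56 to 0.12, Alpi -2.91 to 2.30, the PAF partners and DNA replication list -0.027 to 0.53, the DNA damage repair list -0.011 to 0.41, the absorptive enterocyte list -1.67 to 0.26. A log2 change of 2 was recovered in 3.0% of simulated genes at this spread, so smaller changes were mostly out of reach.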

Other observations

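The tests of the share of tumour epithelium, of stem cells and of sex in the Wnt list were chosen after the result was seen, as were the Hox, gastric, squamous and Reg genes and the 2-fold rule described here; the tests of short transcripts, of GC content and length, and of sex chromosome transcripts were written before their results were seen. The 95% intervals over list members were added after the medians had been seen.

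Values of Hox genes, which pattern the body axis, are given by cluster, with no test of the clusters. Of 7 tested Hoxa genes, 6 were higher in both knockout libraries than in both controls, and of 8 tested Hoxb genes, 7 were lower in both, while of 3 tested Hoxc genes 0 were higher and 0 lower in both. Hoxa2, Hoxa6 and Hoxa9 read below 1 FPKM in both controls and passed the filter only through the knockouts. Hoxb3 and Hoxb8 read below 1 FPKM in both knockouts and passed only through the controls. The counts of Hox genes, like those for the Wnt and oxidative phosphorylation lists, have no share over all tested rows beside them. The controls differed from each other by a median of 0.09 and from the knockouts by 0.26 to 0.53, which makes rows without overlap more likely. Hoxa9 read 0.399 and 0.526 FPKM in the controls and 3.10 and 2.70 in the knockouts, and Hoxb9 read 21.2 and 19.1 against 0.0288 and 2.88. The directions of the tested Hoxa and Hoxb genes held under quantile scaling, median centring and TPM. The list of squamous and gastric epithelium was not called (camera adjusted p = 0.175; medians 1.82 and -0.09 in the knockout libraries), though it was called higher without knockout library 2 (adjusted p = 5.29e-05). The list of fetal-like and regenerative epithelium was not called (adjusted p = 0.178), but was without knockout library 2 (adjusted p = 0.00421). Of 12 squamous and gastric members, 5 were higher in both knockouts than in both controls and 3 were lower, and adjusted over the list alone 2 were higher and 1 was lower. The gastric gene Tff2 read 1.12 and 1.55 FPKM in the controls and 116 and 18.6 in the knockouts, Gkn1 read 3.73 and 4.13 against 43.6 and 20.9, and Reg3b, outside that list, read 947 and 962 against 2354 and 4564. The squamous keratins Krt4 and, outside that list, Krt6a were lower in both knockouts, at 5.46 and 5.19 against 0.954 and 1.82 FPKM and at 7.84 and 9.19 against 0.578 and 0.845 FPKM. None of these genes was past the threshold in limma.

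At least 2-fold differences in FPKM + 1 between both knockouts and both controls were seen for 287 protein-coding rows, 67 higher and 220 lower. The other 2 splits of the 4 libraries into pairs gave 9 and 16 such rows. Each of them puts the control libraries on opposite sides, and these libraries differed by a median of 0.09 on the log2 scale. Few rows could pass there whatever the effect of genotype, so those splits give no measure for the 287. With 3 splits, no share under 0.05 can be reached.

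Most called rows were microRNA or small nucleolar RNA rows listed at 0 in both knockout libraries. Among such rows with a mean of at least 10 FPKM, 34 of 84 (40.5%, exact 95% interval 29.9 to 51.7) were listed at 0 in one control and above 10 FPKM in the other, against 1 of 7131 protein-coding rows. This is what unstable estimates for short transcripts would give, and they may account for these calls. Called rows such as Snord47 (416 and 313 FPKM in the controls), Mir2861 (98.6 and 74.3) and Mir3061 (58.5 and 44.1) fell alike. The estimated worth of 1 fragment, in FPKM times kb, fell likewise from 0.0765 in control library 1 to 0.0572 in control library 2. Equal, small numbers of fragments in both controls would give such values, while Mir22 and Mir3074-1 read higher in control library 2. A loss of these RNAs in the knockout adenomas was not tested separately. Rows that may rest on few fragments cannot decide it.

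Knockout library 2 stood apart from the other 3 libraries. Over protein-coding rows, the robust SD of its log2 ratio to the control mean was 2.11 times that of knockout library 1. Without chromosomes X and Y the ratio was again 2.11, but this removed 372 of 12583 rows, too few to move a robust SD, so the test decides nothing about sex chromosome transcripts. A trend on GC content and length held 24.0% of the variance of that log2 ratio in library 2 and 4.1% in library 1. Removing it left a ratio of 1.61 (95% interval over rows 1.57 to 1.66), so the fitted trend could be part of the difference but not the whole. The interval does not measure the spread between animals, and GC or length bias outside the fitted trend stays open. The sex of the animal and the makeup of the sample stay open.

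The lower Wnt/beta-catenin list was set against technical and cellular explanations. With the GC and length trend removed, the list median was -0.79 (95% interval over members -1.02 to -0.40; camera adjusted p = 1.40e-08) against -0.81 before, which argues against that trend as the whole cause; it was -0.90 in knockout library 1 and -0.63 in library 2, where the interval of -0.999 to -0.189 leaves a part open. A lower share of tumour epithelium would raise markers of every other cell type if their proportions to each other stayed the same. Medians of fibroblasts (0.20 and 0.63), smooth muscle (0.13 and 1.34), endothelium (0.28 and 0.45) and neutrophils (1.77 and 1.24) were higher. In library 1 the 95% intervals held 0 for fibroblasts (-0.095 to 0.344), smooth muscle (-0.039 to 0.193) and endothelium (-0.321 to 0.365). Medians of mast cells were -1.04 and -1.11, with intervals below 0. T cell and NK cell medians were -0.94 and -0.48, with an interval of -0.861 to 0.055 in library 2. Macrophage and dendritic cell medians were -0.32 and 0.75. The mast cell medians cleared the bound of -0.4 set for this test. A later rule that the interval clear it too was not met in library 2 (-1.50 to -0.15), so the test rests on the lists moving apart. Only neutrophils had intervals above 0 in both libraries, and only mast cells had intervals below 0 in both. Immune cells can change in number apart from the tumour share, and lists of normal epithelium were not part of the test. The test therefore argues only against a joint rise of all the other cell types, and a lower tumour share stays open. Fewer stem cells would lower stem cell markers outside the Wnt list. Their median was -0.21 in library 1 (95% interval -0.39 to 0.17) and 0.54 in library 2 (95% interval 0.05 to 0.94). Only library 2 goes against this explanation, and a fall in library 1 is not excluded. Sex does not account for the lower list in knockout library 1, which matched the controls in Xist and Eif2s3y and had a median of -0.98 (95% interval -1.22 to -0.60), while in library 2 sex stays open, as do the PAF genotype and markers of intestinal position in both libraries.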
